A study of Mus musculus with 8 samples.

How the data were processed

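RNA of the whole caput epididymis was profiled in 8 libraries, 4 from wild-type (WT) and 4 from Nell2-knockout (Nell2-KO) C57BL/6N mice at 14 weeks of age. Per the labels' protocols, the tissue was flash frozen, its RNA was extracted on columns and amplified in a single linear round, and stranded mRNA libraries were read on an Illumina GAIIx as single 36-base reads. Groups and replicate numbers were taken from the sample titles. The labels describe replicates of a genotype and do not say that each came from a separate animal.

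The authors deposited raw read counts per gene symbol and library, per the file headers. The submitters' processing notes name CASAVA 1.8.2, FastQC 0.11.2, Bowtie2 2.2.0 and the mouse build mm10. The counting tool, its annotation, its strand setting and its treatment of reads that fit several places are not given in the sources used here. The authors also deposited RPKM values, per the file headers. For every gene the ratio of count to RPKM differed between libraries by a constant that was not the ratio of the summed counts, so the authors' RPKM were scaled to another total. This total, relative to the counts in genes, gave each library's share of reads in gene counts. The authors' deposited fold change is the ratio of mean RPKM in Nell2-KO to that in WT, and the deposited p-value is an unadjusted comparison of the same RPKM values. Both were used only where the authors' deposited table is named.

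The counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, edgeR's default expression filter, robust dispersion estimates and the quasi-likelihood F test of genotype, without covariates. Benjamini-Hochberg adjustment ran over the 11062 genes that passed the filter, and a gene was called at an adjusted p under 0.05. CPM were computed from the library totals multiplied by the TMM factors. Standard errors of log2 fold changes were derived from the fold change and the F statistic. A gene with 0 reads in a group was given a floor of 3 counts over the pooled group, and one with 1 to 3 reads a ratio of pooled scaled counts with an exact binomial 95% interval. Floors and intervals cover counting error only, since the reads carry no molecular identifiers and the RNA was amplified. Library totals ran from 801112 to 6256204 counts, so that the floor in a single library ran from 0.457 to 4.22 CPM.

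The groups, the test, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The 29 lists were initial segment genes, caput genes beyond the initial segment, ERK pathway feedback and target genes, beta-defensins, lipocalins, cystatins, the RNase A family, ADAM proteases, and WFDC, SPINK and serpin inhibitors. They further held androgen response, ion and water transport, oxidative defence, unfolded protein response, cholesterol synthesis, proliferation, interferon response and immediate early genes, and genes flanking Nell2. The markers were of germ cells and sperm, smooth muscle, fibroblasts, macrophages and dendritic cells, lymphocytes, endothelium, basal cells, clear cells, ciliated cells, adipocytes and erythrocytes. Families were taken by symbol pattern, and the pattern for cystatins also took 4 cleavage stimulation factor genes. Several genes belong to more than 1 list. Lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the 26 lists with enough tested members, and again with an estimated correlation and with fry. Camera compares a list with the other genes, while fry asks whether its members move 1 way on balance and makes no such comparison. Adjustment over a list alone is more lenient than over all genes where the list holds a larger share of called genes. Equal numbers called in such a list are therefore no check of the calls.

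The rule named Nell2, Ovch2, Adam28 and Ros1, then the 10 higher and 10 lower genes with the largest fold change among called genes without overlap between groups and with at least the median level. It left out numbered gene models and small RNAs. It then named up to 4 members of each list by adjusted p. Some genes that the rule names are not reported here. Defb15, Ggt1, Defb42, Egr1, Spry2, Clu, Gpx5, Lcn6, Lcn12, Defb18, Spink10, Slc9a2, Car2, Acta2 and Myh11 fall outside the rule and were chosen after their values were seen.

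Gene positions, overlaps and GC content came from GENCODE M21 on mm10, to which 22681 of 24059 symbols matched directly and 23674 after synonyms were followed. GC content was that of a gene's longest transcript and was known for 99.4% of the genes tested. A library's mean GC content weights these values by its counts, and read sequences were not examined. Pairs of libraries were compared by a chi-square of their counts. The lowest value per degree of freedom was 1.29, for WT replicates 3 and 4, and other pairs within a group gave 2.09 to 18.4. The lowest value is close to that of repeated sampling of the same RNA. It therefore does not show that WT replicates 3 and 4 came from separate animals. The chi-square also rises with depth, so it does not rank pairs of unlike depth. By correlation of log CPM, WT replicates 3 and 4 (0.9813) were no closer than WT replicates 1 and 3 (0.9817) or Nell2-KO replicates 3 and 4 (0.9827). No library was left out as a copy of another, and the test treats all of them as separate replicates.

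Alternatives were RLE scaling, library totals alone, no filter, a filter at a mean of 50 counts, DESeq2 1.42.0, voom with sample quality weights, the replicate number as a block, the 20 genes with the highest mean left out, each library left out, and other thresholds. Chosen after seeing the data were the omission of both outlying libraries (WT replicate 2 and Nell2-KO replicate 1), thinning of all libraries to 801112 counts, removal of a loess trend on GC, and limma on log2 of the authors' RPKM plus 1. That limma fit added no scaling between libraries, and the RPKM of Nell2-KO replicate 1 summed to 130913, against 250660 to 305948 in the other libraries. The edgeR step was tested on simulated data for the Nell2-KO against WT comparison, with 10840 genes passing the filter. It called 60 of 95 genes simulated at 2-fold (63.2%), 89 of 93 at 4-fold (95.7%) and 12 of 10652 unchanged genes (0.113%).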

Results

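The transcriptome of the caput epididymis, the proximal part of the duct in which sperm mature, was sequenced in 4 wild-type (WT) and 4 Nell2-knockout (Nell2-KO) samples from C57BL/6N mice aged 14 weeks. Each library was read as single 36-base reads after an amplification of the RNA. The deposited table held read counts for 24059 gene symbols, of which 5874 had 0 reads in all 8 libraries. Counts summed to 2517387, 2073811, 2079471 and 2176667 in WT replicates 1 to 4 and to 801112, 1308439, 6256204 and 5416458 in Nell2-KO replicates 1 to 4. The labels describe the replicates only by number, so that p-values measure the spread between these samples. Levels below are TMM-scaled CPM, as mean ± SD with n = 4 per group unless stated otherwise. Folds are edgeR's fitted values, which can differ from the ratio of the mean CPM, unless a floor or a ratio of scaled counts is named.

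Nell2 encodes a secreted glycoprotein made by germ cells of the testis, and the comparison asks how its loss changes transcripts of the caput. The gene (ENSMUSG00000022454.17) lies on chromosome 15 at 95075230 to 95528559 of mm10, on the minus strand. It had 0 reads in each of the 4 WT and each of the 4 Nell2-KO libraries. A count of 0 allows up to 3 reads, which is 0.339 CPM over the pooled WT libraries and 0.211 CPM over the pooled Nell2-KO libraries, counting error only. Nell2 was therefore under this limit in both genotypes and did not check the genotype labels. Of the 14 genes tested that flank Nell2, Slc38a1 (19.95 ± 3.38 to 6.77 ± 2.49 CPM), Slc38a2 and Pphln1 fell and Tmem117 rose (9.51 ± 1.77 to 21.8 ± 3.55 CPM). Adjusted over the list alone, 3 fell and 2 rose. Leaving out Nell2-KO replicate 3 gave 2 higher and 2 lower members, and limma on the authors' RPKM called 0 of 13. Without scaling between libraries, that limma fit called 54 of 11101 genes higher and 448 lower in all. Camera did not call this list (adjusted p = 0.99), whose median log2 fold change was 0.05 and mean -0.03, with camera's direction lower. The call of Pphln1 ended without Nell2-KO replicate 3 or 4 (edgeR adjusted p of up to 0.0683, without Nell2-KO replicate 3).

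Of 17 genes tested that mark the initial segment, the most proximal stretch of the caput, 13 fell and 2 rose in Nell2-KO. Ovch2, which encodes an ovochymase-type secreted serine protease, fell 33.2-fold, from 1947 ± 136 CPM to 59.8 ± 11.8 CPM. Adam28, which encodes a transmembrane ADAM protein, fell from 4939 ± 343 CPM to 6.16 ± 10.9 CPM. Gldn, which encodes gliomedin, rose 8.42-fold, from 24.0 ± 5.16 CPM to 203 ± 26.4 CPM. Clu, which encodes the secreted chaperone clusterin, rose from 6964 ± 1858 CPM to 19636 ± 2072 CPM. Of 11062 genes tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 1654 (15.0%) changed, 690 of them higher and 964 lower in Nell2-KO. The median log2 fold change was 0.98 among the genes that rose and -1.22 among those that fell, against 0.03 over all genes tested. At least a 2-fold change was seen for 331 of the genes that rose and 600 of those that fell, and 181 genes fell at least 8-fold. In 1531 of the 1654 genes the 4 values of each group did not overlap. Such separation was seen in 22.1% of all genes tested and is expected for 2.86% by chance.

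**Figure D1:**
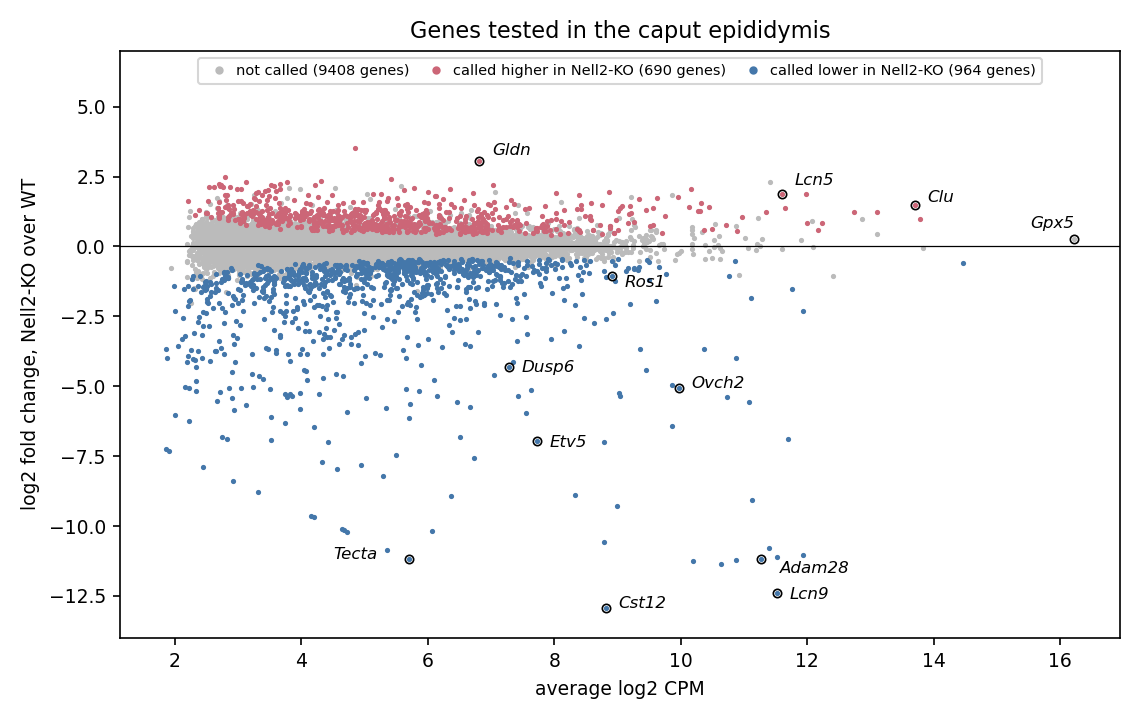
Fitted log2 fold change of Nell2-KO over WT against the average log2 CPM, 1 point per gene tested, with genes called by edgeR in colour and 12 genes circled. Among the 964 genes called lower, Adam28 lies at -11.17, and Gldn lies at 3.07 among the 690 genes called higher; fitted values of genes with 0 to 3 reads in a group, such as Tecta and Cst12, depend on the prior count.

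The number of calls depended on Nell2-KO replicate 1, which had the lowest total and stood apart from the other 3 Nell2-KO libraries. Its share of reads in gene counts was 0.496 of the WT mean, against 1.02 to 1.03 in the other 3. The mean GC content of annotated transcripts, weighted by its counts, was 45.5%, against 46.8% to 47.0%. This mean depends on which genes were counted and is not the GC content of the reads. Without Nell2-KO replicate 1, 1249 genes were called higher and 1541 lower, and 1628 of the 1654 calls were kept. Without it and without WT replicate 2, which held 7158 CPM of Malat1 against 985 to 1129 CPM in the other 3 WT libraries, 1391 genes were called higher and 1694 lower, with 1610 of the calls kept. The number of higher calls was 443 without WT replicate 1 and 456 without WT replicate 3.

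Of the 17 initial segment genes tested, 13 fell, 2 rose and 2 did not pass the test, with a median log2 fold change of -5.05. Adjusted over the list alone, 13 fell and 3 rose. Cst12, Cst8 and Cst11 encode cystatin-type protease inhibitors, and fell from 898 ± 130 to 0.352 ± 0.704 CPM, from 2330 ± 280 to 2.04 ± 2.47 CPM and from 4248 ± 928 to 89.2 ± 22.7 CPM, respectively. The lipocalins Lcn8 (5876 ± 1316 CPM in WT) and Lcn9 (5860 ± 748 CPM in WT) fell to 5.56 ± 8.50 and 3.92 ± 7.72 CPM. Rnase10, a member of the RNase A family, fell from 7767 ± 466 to 5.89 ± 7.37 CPM. The size of these falls rested on few reads in Nell2-KO: without Nell2-KO replicate 1, the log2 fold change went from -11.17 to -13.30 for Adam28, from -12.40 to -15.66 for Lcn9, from -11.12 to -12.14 for Lcn8 and from -11.24 to -11.83 for Cst8. Without Nell2-KO replicate 3 it was -10.32 for Adam28, -11.41 for Lcn9 and -10.36 for Cst8, and without Nell2-KO replicate 4 it was -10.36 for Adam28 and -11.68 for Lcn9. Cst12 had 7948 reads in the pooled WT libraries and 1 read in the pooled Nell2-KO libraries, a ratio of scaled counts of 12767 with a 95% exact binomial interval of 2291 to 504325.

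Ros1, which encodes a receptor tyrosine kinase of the initial segment epithelium, fell less, by 1.06 ± 0.17 on the log2 scale (SE), from 651 ± 69.4 to 312 ± 63.9 CPM (edgeR adjusted p = 0.00095). The adjusted p was 8.6e-09 for Ovch2 and 1.1e-05 for Adam28 in the same edgeR test. In mm10, Ovch2 (ENSMUSG00000048236.8) lies on chromosome 7 at 107781544 to 107801208, Adam28 (ENSMUSG00000014725.16) on chromosome 14 at 68606027 to 68655842, and Ros1 (ENSMUSG00000019893.13) on chromosome 10 at 52045721 to 52195244, each on the minus strand. The list as a set was lower than other genes by camera with a preset correlation (adjusted p = 1.2e-43 over 26 lists), and with an estimated correlation its camera adjusted p was 0.00101. The 2 members that rose were the beta-defensin Defb15, from 290 ± 144 to 756 ± 236 CPM, and Ggt1, which encodes a gamma-glutamyltransferase, from 61.3 ± 17.1 to 127 ± 48.0 CPM. The call of Defb15 ended without any of 7 of the 8 single libraries, with an edgeR adjusted p of up to 0.107 (without Nell2-KO replicate 2), and that of Ggt1 without any of 6, with an edgeR adjusted p of up to 0.0742 (without Nell2-KO replicate 4). Leaving out any single library left 0 or 1 of the list's members called higher and 13 called lower. Rnase9 and Defb42 did not pass the test. Rnase9 was at 913 ± 595 CPM in WT and 4545 ± 3382 CPM in Nell2-KO.

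**Figure D2:**
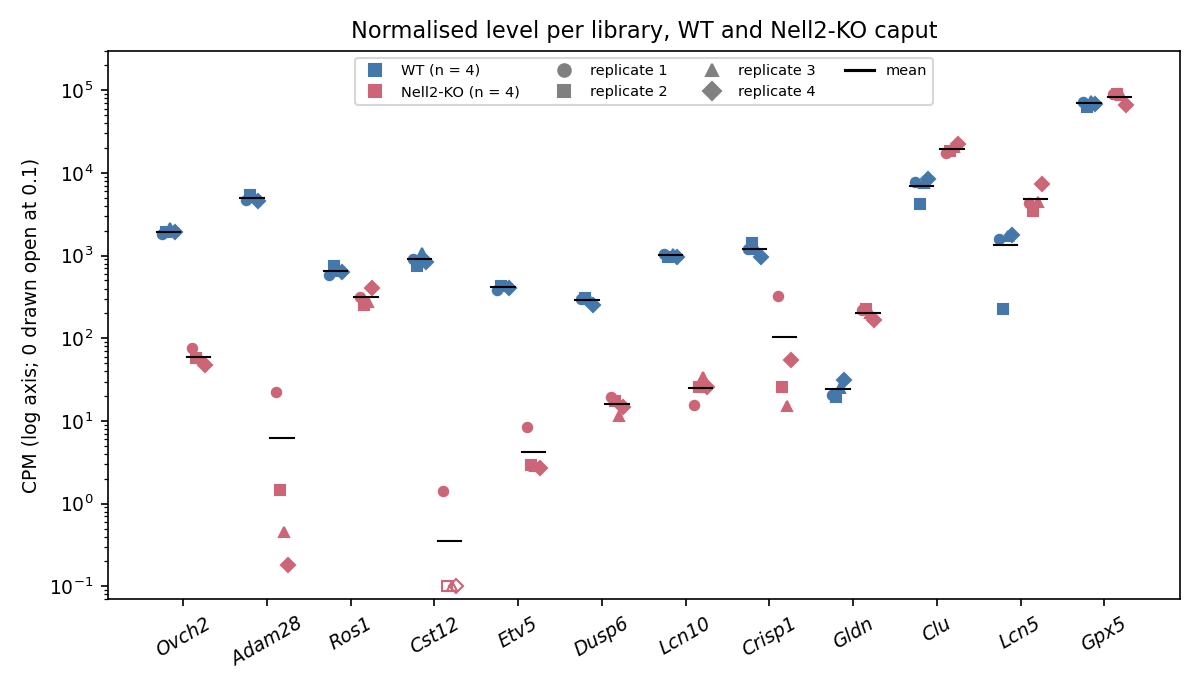
TMM-scaled CPM on a log axis for 12 genes, 1 point per library (WT blue, Nell2-KO red, 1 marker shape per replicate number, 0 drawn open at the foot of the axis), with a bar at the mean of the 4 libraries. For Adam28 the 4 WT libraries lie between 4629 and 5336 CPM and Nell2-KO replicate 1, at 22.5 CPM, lies above the other 3 Nell2-KO libraries, at 0.180 to 1.45 CPM.

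Of the 15 ERK pathway feedback and target genes tested, 13 fell and 0 rose, also when adjusted over the list alone, which is more lenient here. The ETS factor Etv5 fell 126-fold in the edgeR fit, with mean levels of 413 ± 19.99 CPM in WT and 4.24 ± 2.81 CPM in Nell2-KO. Etv4, another ETS factor, fell from 41.2 ± 10.8 to 0.166 ± 0.193 CPM, and its level in Nell2-KO rested on 4 reads over the 4 libraries, against 369 in WT. Dusp6, which encodes a phosphatase that acts on ERK, fell 19.7-fold, from 291 ± 24.9 to 15.8 ± 3.53 CPM. Spred1, an inhibitor of the pathway, fell 4.11-fold. Etv4 was also a member of the initial segment list. The median of the list was -2.15, and it was lower than other genes by camera (adjusted p = 4.5e-31 with the preset and adjusted p = 0.021 with an estimated correlation). Egr1 and Spry2 did not pass the test. Spry2 was at 92.9 CPM in Nell2-KO replicate 1 and at 11.6 to 14.0 CPM in the other 3 Nell2-KO libraries, and without that library its log2 fold change went from 0.15 to -0.74 (edgeR adjusted p = 0.0134). Egr1 was at 93.3 ± 24.6 CPM in WT and 54.9 ± 50.2 CPM in Nell2-KO, and without Nell2-KO replicate 4 its log2 fold change went from -0.63 to -1.44 (edgeR adjusted p = 0.0198).

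Of 21 caput genes beyond the initial segment tested, 9 rose, 6 fell and 6 did not pass the test, while limma on the authors' RPKM called 0 higher and 5 lower. The limma fit had no scaling between libraries and called only 54 of 11101 genes higher in all. From the counts, adjusted over the list alone, 9 rose and 7 fell. Lcn10, a lipocalin, fell 38.0-fold, from 1010 ± 51.5 to 25.1 ± 7.56 CPM. Teddm1 fell 41.4-fold, Ly6g5b fell 30.8-fold and Ly6g5c, like it a member of the Ly6 family, fell 8.75-fold. Lcn5, which encodes a retinoic acid-binding lipocalin, rose 3.69-fold, from 1325 ± 738 to 4893 ± 1726 CPM. Its WT values included 226 CPM in WT replicate 2, against 1570 to 1775 CPM in the other 3. The call of Lcn5 ended without WT replicate 1, WT replicate 3, Nell2-KO replicate 1 or Nell2-KO replicate 4, with an edgeR adjusted p of up to 0.130 (without Nell2-KO replicate 1). Gpx5, the secreted glutathione peroxidase that was the most abundant transcript of this list, had a log2 fold change of 0.27 ± 0.17 (SE, edgeR adjusted p = 0.36). The list's median log2 fold change was 0.27, while its mean was -0.56 and camera gave its direction as lower (adjusted p = 0.107, and 0.63 with an estimated correlation). The camera adjusted p became 0.0073 without Nell2-KO replicate 1 and 0.00746 when WT replicate 2 was also left out. In these 2 fits 4 and 6 of the list's members were called higher and 6 called lower. The number of members called higher was 4 without WT replicate 3 and 5 without WT replicate 1, Nell2-KO replicate 3 or Nell2-KO replicate 4.

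Of 19 beta-defensin genes tested, 6 rose and 5 fell, while limma on the authors' RPKM called 0 of 29 higher and 6 lower. Over all 11101 genes of that fit, which had no scaling between libraries, only 54 were called higher. The 5 that fell were Defb48 (3724 ± 246 to 4.18 ± 7.55 CPM), Defb25 (1016 ± 264 to 1.88 ± 1.94 CPM), Defb47 (868 ± 57.1 to 6.41 ± 4.87 CPM), Defb20 (6497 ± 324 to 1295 ± 369 CPM) and Defb18 (1237 ± 95.6 to 319 ± 91.8 CPM). Adjusted over the list alone, 9 rose and 5 fell. The number called higher was 1 without WT replicate 1, 2 without WT replicate 3 or 4, 3 without WT replicate 2 or Nell2-KO replicate 2 or 4, and 4 without Nell2-KO replicate 1 or 3. Without Nell2-KO replicate 3 the log2 fold change of Defb48 went from -11.22 to -10.36, and without Nell2-KO replicate 1 to -12.71. Without Nell2-KO replicate 4 that of Defb25 went from -9.30 to -10.15 and that of Defb47 from -6.99 to -7.87. Of 7 lipocalins, Lcn8, Lcn9, Lcn10 and Lcn2 fell and Lcn5 and Lcn12 rose, and adjusted over the list alone 2 rose and 4 fell. The number of lipocalins called higher was 1 without WT replicate 1 or 3 or Nell2-KO replicate 1 or 4, and 0 by limma on the authors' RPKM. Of 9 genes with cystatin-like symbols, 3 fell and 0 rose, also when adjusted over the list alone. The 3 were Cst8, Cst11 and Cst12. The other members included Cst3, at 207 ± 20.1 and 147 ± 50.7 CPM, and 4 subunits of the cleavage stimulation factor, which are not cystatins. Of 7 RNase A family genes, Rnase10 fell and Rnase13 rose (2 rose and 1 fell when adjusted over the list alone). Without Nell2-KO replicate 1, 0 of these rose and 2 fell, and on the authors' RPKM 0 rose and 1 fell. Of 7 ADAM genes, Adam28 and Adam7 fell, and 2 fell when adjusted over the list alone. Adam7 went from 26980 ± 881 to 18018 ± 3234 CPM. Its call ended without any of 7 single libraries (edgeR adjusted p of up to 0.138, without Nell2-KO replicate 3) and with RLE scaling (edgeR adjusted p = 0.0511).

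Of 30 protease inhibitor genes of the WFDC, SPINK and serpin families tested, 16 rose and 2 fell, while limma on the authors' RPKM called 0 of 34 higher and 2 lower. That fit, without scaling between libraries, called only 54 of 11101 genes higher in all. The numbers from the counts were the same when adjusted over the list alone. Spink5, which encodes a Kazal-type inhibitor, rose 2.62-fold, from 1785 ± 68.1 to 4671 ± 663 CPM. Wfdc11 rose 2.45-fold and Wfdc3 rose 4.97-fold, the latter from 4.31 ± 1.86 to 19.3 ± 8.21 CPM. Spink13 fell 5.95-fold and Spink10 fell by 0.60 ± 0.18 on the log2 scale (SE). The call of Spink10 ended without any of 5 single libraries, with an edgeR adjusted p of up to 0.145 (without WT replicate 3). By camera, the set was higher than other genes (adjusted p = 0.0015 with the preset correlation) and was not called with an estimated correlation (adjusted p = 0.32). Camera called the lipocalins (adjusted p = 2.9e-05) and the cystatin-like symbols (adjusted p = 1.4e-12) lower, and both held with an estimated correlation (adjusted p = 0.021 and 0.0033). Beta-defensins (adjusted p = 0.23, median 0.82, mean -0.92), RNase A genes (adjusted p = 0.23, median 0.29, mean -0.96) and ADAM genes (adjusted p = 0.27) were not called by camera, which gave their direction as lower. Without Nell2-KO replicate 1 the camera adjusted p was 0.00942, 0.0073 and 0.000431 for these 3 lists, and with WT replicate 2 also left out it was 0.000102, 0.0108 and 8.3e-05. The camera adjusted p was also under the threshold for beta-defensins without Nell2-KO replicate 4 (0.016) and with all libraries thinned to one depth (0.000137), and for RNase A genes with thinning (0.0391) and without a filter (0.0399). For ADAM genes it was 0.00942 with voom weights and 0.0115 on the authors' RPKM. Members of these families share sequence, and their counts are uncertain where 36-base reads fit several members, since the handling of such reads is not given in the sources used here.

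**Figure D3:**
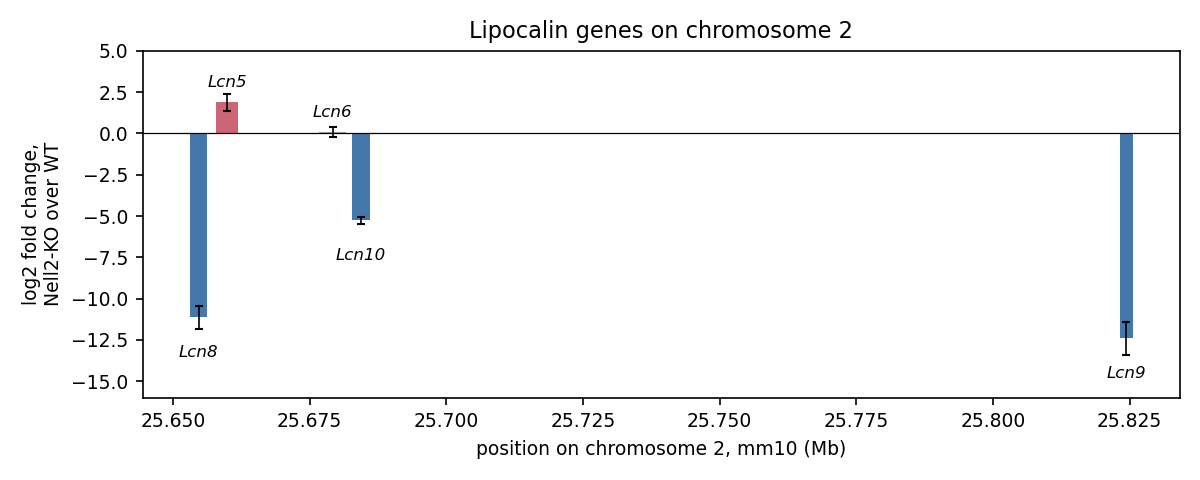
Fitted log2 fold change of Nell2-KO over WT, as bars with the SE, for the 5 tested lipocalin genes of 1 stretch of chromosome 2, at their mm10 positions in Mb (called lower blue, called higher red). Lcn8 lies at -11.12 and its neighbour Lcn5 at 1.88.

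**Figure D4:**
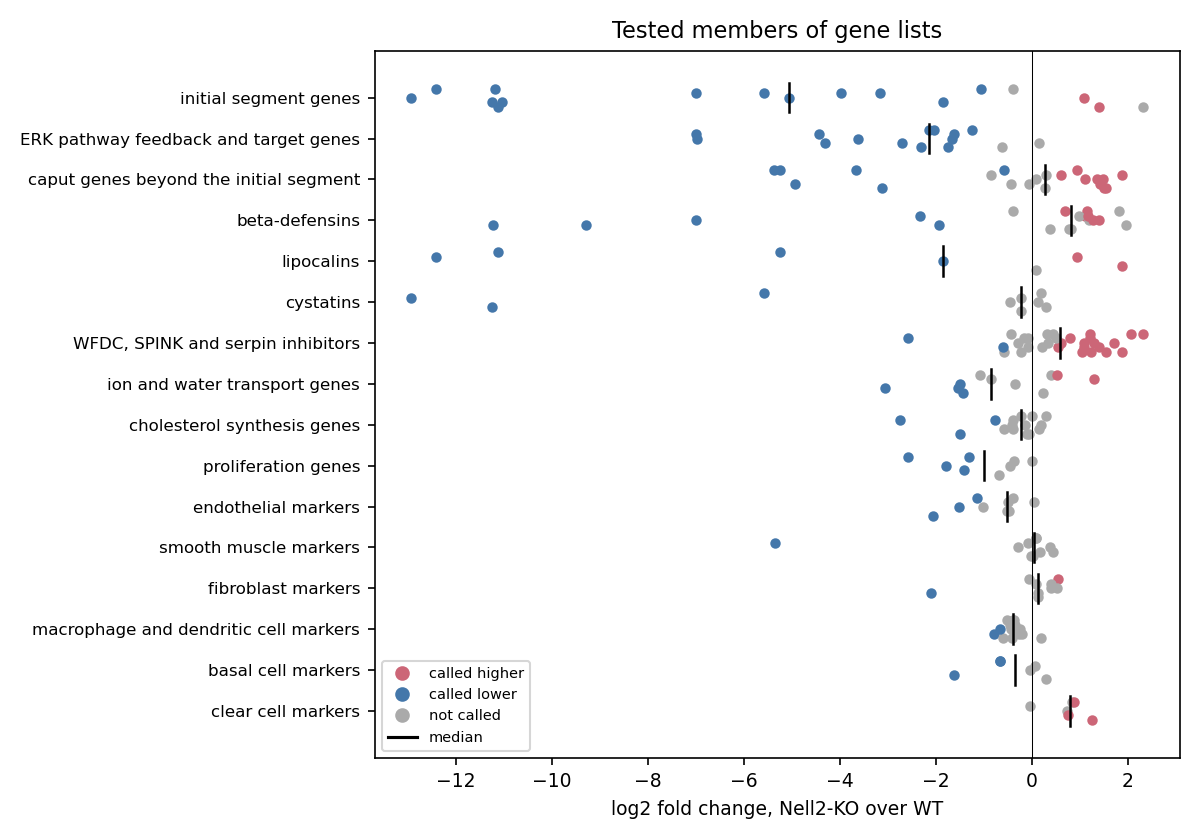
Fitted log2 fold change of Nell2-KO over WT for the tested members of 16 gene lists, 1 point per gene, with the median as a bar and edgeR calls in colour. Of the initial segment genes 13 of 17 and of the ERK pathway genes 13 of 15 lie among the genes called lower.

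Among the other genes with the largest falls, Tecta (101 ± 5.64 CPM in WT) and Gria2 (79.8 ± 14.7 CPM in WT) had 0 reads in the pooled Nell2-KO libraries. Against a floor of 3 counts over the group, Tecta, which encodes alpha-tectorin, was at least 480-fold lower, and Gria2, which encodes a glutamate receptor subunit, was at least 377-fold lower. The keratin gene Krt23 had 1159 pooled reads in WT and 1 in Nell2-KO, a ratio of scaled counts of 1862 with a 95% exact binomial interval of 333 to 73596.

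The largest increases were smaller than the largest falls. At least an 8-fold rise was seen for 2 genes and at least an 8-fold fall for 181. The highest log2 fold change was 3.52 and the lowest -12.93. The genes given here are those that the rule for named genes kept. Gc, which encodes the vitamin D-binding protein, rose 5.36-fold, from 13.2 ± 7.08 to 70.7 ± 26.8 CPM. Nxpe2 rose 4.61-fold, Gabra4, a GABA receptor subunit gene, rose 4.28-fold, and Tfap2b, which encodes an AP-2 transcription factor, rose 4.20-fold. Pon3, a paraoxonase gene, rose 4.05-fold, from 19.3 ± 4.64 to 77.0 ± 17.1 CPM, and Tmc5 rose 3.88-fold. Serpina1f, a serpin gene, rose 4.19-fold, Muc5b, a gel-forming mucin gene, rose 3.90-fold and Rnase13 rose 3.77-fold. Without Nell2-KO replicate 1 the edgeR adjusted p was 0.108 for Serpina1f, 0.153 for Muc5b and 0.0533 for Rnase13, so that these calls ended. The call of Muc5b also ended without WT replicate 1, WT replicate 3 or Nell2-KO replicate 4, and that of Serpina1f without WT replicate 1 (edgeR adjusted p = 0.0509). Without Nell2-KO replicate 4 the log2 fold change of Serpina1f went from 2.07 to 1.48. With both outlying libraries left out, Tfap2b was not called (edgeR adjusted p = 0.109). Gabra4 overlaps Gabrb1 and Tecta overlaps an antisense gene model on the opposite strand, and Gria2 overlaps a small RNA gene on its own strand. Reads of opposite strands cannot be told apart here, since the strand setting of the counting is not given in the sources used here. Reads of the same strand, as for Gria2 and its partner, would not be separated by any strand setting.

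Of 11 genes of ion and water transport tested, 4 fell and 2 rose, also when adjusted over the list alone (camera adjusted p = 0.028, and adjusted p = 0.15 with an estimated correlation). Cftr, the chloride channel gene, fell 8.30-fold, from 195 ± 22.9 to 22.6 ± 5.04 CPM, and overlaps an antisense gene model. The sodium bicarbonate cotransporter gene Slc4a4 fell 2.91-fold and the carbonic anhydrase gene Car2 fell by 1.51 ± 0.26 on the log2 scale (SE). The anion exchanger gene Slc26a3 rose 2.45-fold and Slc9a2 rose by 0.53 ± 0.16 on the log2 scale (SE). The call of Slc9a2 ended without any of 6 single libraries (edgeR adjusted p of up to 0.131, without WT replicate 4). Without Nell2-KO replicate 1 the camera adjusted p of the transport list was 0.0564, and it was 0.0565 to 0.127 in 5 other settings, the highest on the authors' RPKM. Of 8 proliferation genes, Mki67 (36.3 ± 16.6 to 5.02 ± 4.47 CPM), Top2a (16.8 ± 2.68 to 5.36 ± 2.36 CPM), Ccna2 and Mcm5 fell, and 6 fell when adjusted over the list alone (camera adjusted p = 0.017, adjusted p = 0.27 with an estimated correlation, and 0.122 with thinning). Leaving out Nell2-KO replicate 1 gave 6 lower members. Without Nell2-KO replicate 4 the log2 fold change of Mki67 went from -2.59 to -3.69. The call of Mcm5 ended without any of 5 single libraries (edgeR adjusted p of up to 0.118, without WT replicate 1) and with library totals alone (edgeR adjusted p = 0.058). The call of Mki67 ended with both outlying libraries left out (edgeR adjusted p = 0.0526).

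Of 10 androgen response genes, 3 fell, among them Crisp1 (12.7-fold) and Adam7, and Lcn5 rose. The same numbers passed when adjusted over the list alone (camera adjusted p = 0.59). The number called lower by edgeR was 2 without WT replicate 1 and 1 without WT replicate 2, 3 or 4 or Nell2-KO replicate 2 or 3. The number called higher was 0 without WT replicate 1 or 3 or Nell2-KO replicate 1 or 4. Crisp1, a cysteine-rich secretory protein gene, was at 1198 ± 180 CPM in WT, at 322 CPM in Nell2-KO replicate 1 and at 15.1 to 55.0 CPM in the other 3 Nell2-KO libraries. Its log2 fold change without Nell2-KO replicate 1 went from -3.67 to -5.20. Of 15 cholesterol synthesis genes, Dhcr7 (6.69-fold), Lss (2.81-fold) and Idi1 (1.71-fold) fell, also when adjusted over the list alone (camera adjusted p = 0.065). Leaving out Nell2-KO replicate 1 gave 8 lower members, and the camera adjusted p was 0.0499 without WT replicate 1, 0.035 without Nell2-KO replicate 3, 0.00833 without a filter and 0.0118 on the authors' RPKM. Of 20 oxidative defence genes, Gpx3 rose and Gpx4 fell, also when adjusted over the list alone (camera adjusted p = 0.50). The list had 3 higher and 3 lower members without Nell2-KO replicate 1, 2 higher members without Nell2-KO replicate 3 or 4, and 2 lower members without WT replicate 2. The call of Gpx4 ended without any of 5 single libraries (edgeR adjusted p of up to 0.0851, without Nell2-KO replicate 3), and that of Gpx3 with both outlying libraries left out (edgeR adjusted p = 0.0705). Of 14 unfolded protein response genes, Asns rose and 0 fell (camera adjusted p = 0.59), and 2 rose and 1 fell without Nell2-KO replicate 1. Of 9 interferon response genes, Irf7 rose and Rsad2 fell (camera adjusted p = 0.27, and 0.0379 on the authors' RPKM), and the call of Rsad2 ended without Nell2-KO replicate 3 (edgeR adjusted p = 0.0633). Of 11 immediate early genes, Egr2 fell, from 490 ± 56.8 to 256 ± 13.9 CPM, and 0 rose (camera adjusted p = 0.75, median 0.17, mean 0.25, with camera's direction lower). Without Nell2-KO replicate 4, 3 members of this list were called lower. For these 3 lists the same numbers passed when adjusted over the list alone.

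Markers of other cell types were measured beside the epithelial genes. Of 9 endothelial markers, Kdr, Pecam1 and Emcn fell, Pecam1 from 26.6 ± 0.529 to 12.2 ± 0.929 CPM, and 4 fell when adjusted over the list alone (camera adjusted p = 0.028, and adjusted p = 0.28 with an estimated correlation). Without Nell2-KO replicate 4 the camera adjusted p was 0.0561, with thinning 0.0603 and without both outlying libraries 0.0728. Of 6 clear cell markers, Car12 rose 2.37-fold, Foxi1 rose 1.84-fold and Atp6v1g3 rose 1.69-fold, and 5 rose when adjusted over the list alone (camera adjusted p = 0.017, and adjusted p = 0.14 with an estimated correlation). Without Nell2-KO replicate 1, 5 members were called higher and 1 lower. Limma on the authors' RPKM called 0 of 7, in a fit that called only 54 of 11101 genes higher in all. The camera adjusted p was 0.0625 with the stricter filter. The call of Atp6v1g3 ended without any of 4 single libraries (edgeR adjusted p of up to 0.122, without WT replicate 3). Of 10 smooth muscle markers only Actg2 was called. It fell 40.7-fold, from 1019 ± 133 to 24.4 ± 5.63 CPM, while Acta2 was at 292 ± 33.7 and 307 ± 31.9 CPM and Myh11 at 187 ± 28.4 and 199 ± 26.0 CPM. Of 9 fibroblast markers, Pdgfra fell 4.31-fold, from 517 ± 42.5 to 121 ± 23.8 CPM, and Dcn rose 1.45-fold. The call of Dcn ended without any of 6 single libraries (edgeR adjusted p of up to 0.124, without WT replicate 3). Pdgfra overlaps antisense gene models.

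Of 6 basal cell markers, Trp63, Cldn1 and Krt15 fell, while Krt5 was at 42.1 ± 6.80 and 49.0 ± 17.8 CPM. Without Nell2-KO replicate 4 the log2 fold change of Krt15 went from -1.63 to -2.62. The call of Krt15 ended without any of 6 single libraries (edgeR adjusted p of up to 0.125, without Nell2-KO replicate 3) and that of Cldn1 without WT replicate 3, WT replicate 4 or Nell2-KO replicate 3 (edgeR adjusted p of up to 0.0621). Of 15 macrophage and dendritic cell markers, Lyz2 and Fcer1g fell. The call of Lyz2 ended without any of 7 single libraries (edgeR adjusted p of up to 0.120, without WT replicate 1), and that of Fcer1g without any of 6 (edgeR adjusted p of up to 0.178, without Nell2-KO replicate 3) and with library totals alone (edgeR adjusted p = 0.0639). The numbers called in the smooth muscle, fibroblast, basal and macrophage lists were the same when adjusted over the list alone. Camera did not call the smooth muscle (adjusted p = 0.23, median 0.05, mean -0.46, direction lower), fibroblast (adjusted p = 0.99), basal cell (adjusted p = 0.27) or macrophage and dendritic cell (adjusted p = 0.17, and 0.0302 on the authors' RPKM) lists. None of the 6 germ cell and sperm markers and 4 ciliated cell markers tested was called by edgeR on all 8 libraries, also when adjusted over the list alone, nor were these lists called by camera (adjusted p = 0.50 and 0.59). At an unadjusted edgeR p under 0.05, 0 of them passed, and DESeq2 and voom with quality weights called 0. With both outlying libraries left out, the ciliated cell marker Rsph1 (6.08 ± 2.98 and 10.4 ± 3.63 CPM over all libraries) was called higher by edgeR, with an adjusted p of 0.0418 against 0.0740 to 0.530 in the other settings that tested it. On the authors' RPKM, camera called the germ cell and sperm list higher (adjusted p = 0.0118, against 0.273 to 0.839 in the other settings). The ciliated cell list had a median of 0.16 and a mean of -0.01, with camera's direction higher. For the lymphocyte, adipocyte and erythrocyte lists 0 members had enough counts to be tested.

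The authors' deposited table also gives a ratio of mean RPKM and an unadjusted p per gene. In the authors' deposited table, 1958 genes had an unadjusted p under 0.05, 384 with a higher and 1574 with a lower mean in Nell2-KO, and 1085 of the 1654 genes called here by edgeR were among them. The edgeR calls use adjusted p-values, so the thresholds are unlike. After Benjamini-Hochberg adjustment of the deposited p-values, 263 of 18185 genes were under 0.05. The median ratio in the authors' deposited table was 0.914. Its RPKM values are scaled to totals that the gene counts do not sum to. In Nell2-KO replicate 1 they summed to 130913, against 250660 to 305948 in the other libraries, which lowers the Nell2-KO mean. The median ratio without this library was not computed. On these RPKM values limma called 54 genes higher and 448 lower, so that 10.8% of the calls were higher against 41.7% of the calls from the counts. The median log2 fold change over all genes was -0.16 in that fit, against 0.03 from the counts. The limma fit added no scaling between libraries, so its few higher calls cannot be separated from the low RPKM of Nell2-KO replicate 1. The authors' deposited table gave a ratio of 0.0267 for Ovch2 and 7.58 for Gldn.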

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

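The splits of the libraries and the tests of GC content and depth were fixed before their results were seen; the tests of leftover transcripts in Nell2-KO replicate 1 and of genes low in WT replicate 2 were chosen after. Except where stated, each CPM, TMM factor, share of reads in gene counts and mean GC content given below for 1 library lay far from the other 3 of its group by Dixon's ratio at 95%. Of 206 groups of 4 values, 37 held such a value. Nell2-KO replicate 1 held 20 of them, WT replicate 2 held 8, Nell2-KO replicates 2 and 4 held 3 each, WT replicate 4 held 2 and Nell2-KO replicate 3 held 1. A rate of 1 in 20 would give 10.3, but it assumes normal and independent values. The groups share libraries of unlike depth, and some genes were chosen after their values were seen, so 10.3 is no chance level. For Cst12 and Krt23 in Nell2-KO, a single read beside values of 0 gives a ratio of 1 by construction.

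Nell2-KO replicate 1 had a TMM factor of 0.886 (1.03 to 1.05 in the others) and a share of reads in gene counts of 0.496 of the WT mean (1.02 to 1.03). The count-weighted mean GC content of annotated transcripts was 45.5% in this library (46.8% to 47.0%). A GC trend explained 27.6% of the variance of its deviations over genes, against 4.47% to 22.6% in the other 3 libraries, a value that leaves GC content open as a part of the cause. Deviations of each library were taken from the mean of the other 3 Nell2-KO libraries. Those of the other libraries thus include Nell2-KO replicate 1 and are no independent baseline. Depth is not the whole cause: with all libraries thinned to 801112 counts the SD of its deviations was 1.72 times the largest of the others. No biological explanation of this library was tested, since its genotype, age and tissue are those of its group.

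Transcripts near 0 in the other Nell2-KO libraries were left in Nell2-KO replicate 1, at 22.5 CPM for Adam28, 18.3 for Lcn8, 16.9 for Rnase10, 15.5 for Lcn9, 15.5 for Defb48 and 1.41 for Cst12. A candidate explanation is 1 small share of wild-type-like RNA or reads. Its 97 reads of 10 such transcripts, chosen without this library, spread as 1 share of 0.335% of the WT level (95% interval 0.271% to 0.408%), with a chi-square of 1.198 per degree of freedom. The test does not separate reads assigned from another library from a few initial segment cells in the tissue. It covers these 10 transcripts only. A share of this size does not account for Crisp1, at 322 CPM in this library against 15.1 to 55.0 CPM in the other Nell2-KO libraries and 1198 ± 180 CPM in WT.

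WT replicate 2 had 7158 CPM of Malat1 (985 to 1129 in the others) and a share of reads in gene counts of 0.900 (1.03 to 1.04). It was low in Lcn5 (226 CPM), Serpina1f (108), Lcn6 (134) and Defb42 (1374), and high in Cst11 (5635) and Mki67 (61.2). Other initial segment genes went both ways in it without reaching Dixon's limit: Lcn8 (7810 CPM) was higher, and Cst12 (758) and Cst8 (1933) were lower, than in each of the other 3 WT libraries. Dissection could add to the genes called higher: of the 511 genes called higher without this library, 12.1% lay at least 1 log2 unit lower in it than in the other WT libraries, against 0.720% of those called lower and 2.77% of all tested. That value lies between the bounds set for the test. The test holds no measure of dissection. It cannot tell dissection from another difference of WT replicate 2, which also stood apart in Malat1 and in its share of reads in gene counts. A genotype effect on the same genes also stays open.

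Of all 35 splits of the libraries into 4 and 4, only the real 1 called 1654 genes by edgeR, and the highest of the others called 0, with up to 1377 genes at an unadjusted p under 0.05. With 35 splits, 1 of 35 is the smallest share this test can give. The other splits mix the genotypes within each group, which raises the spread within groups and lowers their calls. The test therefore does not exclude chance, and it cannot separate genotype from another difference between the groups.

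Further values of Nell2-KO replicate 1 were high in CPM for Atp6v1g3 (107), Crisp1 (322), Emcn (18.3), Etv5 (8.45), Gabra4 (176) and Spry2 (92.9). Its CPM were low for Defb15 (407), Defb20 (746), Ly6g5c (15.5), Teddm1 (22.5) and Wfdc3 (7.04). Nell2-KO replicate 2 was high in Fcer1g (7.27 CPM) and Kdr (13.1) and low in Rnase13 (324). Nell2-KO replicate 4 was low in Gpx5 (65527 CPM) and high in Serpina1f (3699) and Spink10 (167). Nell2-KO replicate 3 held the single read of Krt23 (0.152 CPM), and WT replicate 4 was low in Lcn2 (3098 CPM) and Mcm5 (7.30).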

How the results depend on the processing

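The omission of both outlying libraries, the thinning, the GC correction and limma on RPKM were chosen after seeing the data. None of the 1654 calls was reversed in any setting that tested the gene. Of the 84 called genes named, 66 were tested in all 20 settings, and 37 of these kept their call in each. The other 18 were tested in at least 17 settings each, and 8 of these kept their call where tested; none of the 84 changed sign where tested. The cause was not tested for any change below, except that fewer libraries or counts lower the power. Genes changed numbered 981 at an adjusted p under 0.01, 931 with a 2-fold change, 3484 with voom weights (1596 higher, 1888 lower), 3085 without both outlying libraries (1391, 1694), 986 after thinning (381, 605) and 502 with limma on RPKM (54, 448). Leaving out 1 library gave 1204 to 2790 (443 to 1249 higher, 748 to 1541 lower), the most without Nell2-KO replicate 1. Genes changed at least 2-fold numbered 520 with the stricter filter, which tested 7311 genes, and 463 on RPKM. Of the other gene lists, 7 passed camera, 2 with an estimated correlation, 14 with fry, 3 with the stricter filter and 11 on RPKM. The adjusted p of caput genes beyond the initial segment was 0.0194 with fry, 0.0203 without a filter, 0.00219 without 20 dominant genes, 0.0073 to 0.215 leaving out 1 library, 0.00746 without both outlying libraries and 0.025 with the GC trend removed. The initial segment and ERK lists stayed called in every setting with a list test. Spry2 (0.15) turned to -0.72 with voom weights, -0.74 without Nell2-KO replicate 1 (0.54 at most without another library) and -0.85 without both outlying libraries. DESeq2 gives no list test, and pseudocounts were not varied, since the test used counts.

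With the replicate number as a block, 1184 genes were called (436 higher, 748 lower). Deviations of libraries with the same number correlated at -0.28, -0.17, 0.17 and 0.16 over genes. Pairs with different numbers were not compared, so these values cannot show whether equal numbers pair the libraries. Of the simulated 2-fold changes 63.2% were called, in a simulation at the depth of these libraries. It held far fewer changed genes than were called in the data and no outlying library. Its rates are therefore not those of the real test, and a gene not called is not shown to be unchanged.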

Other observations

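The comparison of neighbouring genes was chosen after their values were seen, and no test of it was run. On chromosome 2 of mm10, Lcn8 (25653120 to 25656217) fell, and Lcn5, which starts 1734 bp further on, rose from 1325 ± 738 to 4893 ± 1726 CPM (SD, n = 4). The call of Lcn5 ended without Nell2-KO replicate 1 (edgeR adjusted p = 0.130), and also without WT replicate 1, WT replicate 3 or Nell2-KO replicate 4. Lcn6 was at 223 ± 60.2 and 235 ± 97.6 CPM, and Lcn10, 1117 bp from it, fell from 1010 ± 51.5 to 25.1 ± 7.56 CPM. Lcn9 fell at the far end of this stretch of 172418 bp.

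On chromosome 14, Rnase10 fell from 7767 ± 466 to 5.89 ± 7.37 CPM, and Rnase9, 27700 bp away on the other strand, was at 913 ± 595 CPM in WT and 4545 ± 3382 CPM in Nell2-KO without passing the edgeR test (adjusted p = 0.095). Rnase11 and Rnase12, further on, had log2 fold changes of -0.45 ± 0.32 and 0.29 ± 0.25 (SE) and did not pass it. On chromosome 2 the cystatin genes Cst11, Cst12 and Cst8 fell, while Cst3, which lies 66126 bp from Cst8 and is active in many tissues, was at 207 ± 20.1 and 147 ± 50.7 CPM.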
